A study of Homo sapiens with 6 samples.

How the data were processed

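RNA from UM-UC-3 cells was sequenced in 6 libraries, 3 labelled negative control and 3 labelled si-CPSF3. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit. The genome build was hg38, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the gene annotation are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner cannot be told apart.

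The authors deposited a table of raw read counts per gene and a table of FPKM values, each with 1 column per library, read by its name as the labels give it. The counts are whole numbers that were not normalised. The deposited FPKM values are scaled to gene length and library size by the authors' own calculation. The ratio of count to FPKM of one gene, taken relative to the median ratio of its library, was not constant over libraries: among 3716 rows with at least 50 counts and an FPKM of at least 1 in every library, it differed by more than 1.2-fold between libraries in 99.9%, with a median range of 1.56-fold. The 2 tables therefore differ in more than scale, and the FPKM values served only as an alternative.

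The tables had 25479 rows for 23382 gene names, as 1338 names stood on several rows marked by a numbered suffix. For 614 of these names the rows held identical counts and for 724 they differed. Each gene was represented by its row with the highest mean count, a choice made after the table was seen, which kept 4145385 to 4378899 counts per library. Of the names, 23014 matched the RefSeq gene table of GRCh38.p14, which supplied gene types and positions.

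Before averaging, replicates of each group were compared by a chi-square test of their counts. The statistic per degree of freedom lay between 6.69 and 16.4, so no pair agreed within sampling noise and each library counted once. The interval of CPSF3 comes from its standard error in the fit, which includes the spread between libraries. A count of 0 was given a floor of 3 counts over the group, which covers counting error only.

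The main test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit, glmQLFTest) in R 4.3.3 on the raw counts, with TMM factors, the default expression filter by group, group as the only term and Benjamini-Hochberg adjustment over 11069 genes, two-sided at 0.05. Standard errors are the absolute log2 fold change divided by the root of F. The common biological coefficient of variation was 0.196. CPM values are counts scaled to the TMM-adjusted library size, and ± is the SD of 3 libraries. CPSF3 also had a two-sided exact permutation test of its CPM. On simulated counts for 10694 genes with 100 genes changed at each size, the test recovered 54% of 2-fold and 94% of 4-fold changes among genes of at least 5 CPM, and 6.33% of its calls were false.

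A total of 31 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided and adjusted over lists, with an estimated correlation and the fry test as alternatives. Fry tests whether the members of a list move on balance one way, without comparing them with other genes. The named genes were CPSF3, then the 12 higher and 12 lower protein-coding genes with the largest change among those past the threshold, with a mean of at least 5 CPM and groups that did not overlap. To these were added the 5 higher and 5 lower with the smallest p, and in each list up to 4 members past the threshold with the largest change at a mean of at least 1 CPM. Where no member passed, the 2 most abundant were named. LOC283299 and RGL2 were named outside this rule, after their values were seen, as were the genes of the closing section.

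The alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and glmTreat against a 1.2-fold change. Chosen after seeing the data were a fit of all rows as deposited, a fit with the distinct rows of a gene summed, and a fit without ribosomal protein, mitochondrial and MALAT1 genes. The count of changed genes was recomputed for all 10 splits of the 6 libraries into 3 and 3.

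For the closing section, 3' UTRs were taken from GENCODE 29 on GRCh38 as the longest 3' UTR among the principal transcripts of a gene, or among its other coding transcripts where none is marked principal. Of 7123 protein-coding genes with at least 5 CPM that do not encode ribosomal proteins, 6790 had a 3' UTR of at least 50 bases, and 6837 genes entered, as names without a protein-coding RefSeq type were kept where GENCODE gives a coding transcript. Log2 fold changes had their extremes clipped and were adjusted for UTR length, GC content and expression. For each 7-base word found in at least 30 genes and missing from at least 30, the score is the difference of the adjusted means of genes with and without the word, divided by its standard error, and the fold changes were shuffled over genes 100 times. Downstream genes were tested genes whose start lies within 5 kb of the end of a tested gene on the same strand. Neighbouring calls were called genes with another gene called in the same direction within 100 kb. The last 2 were each set against 10000 random gene lists matched on expression. Python 3.11.15 with numpy 2.4.6 was used for these steps.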

Results

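Gene expression was measured by RNA sequencing in UM-UC-3, a cell line established from a human bladder cancer. The series held 6 libraries in 2 groups: 3 labelled as negative control and 3 labelled as receiving an siRNA against CPSF3, the endonuclease that cleaves pre-mRNA ahead of polyadenylation. The labels number the libraries of each group 1 to 3 and do not say whether these came from separate cultures, so the p-values measure the spread between these libraries, which can be technical. Total counts lay between 4145385 and 4378899 per library, with means of 4223752 ± 120340 (SD, n = 3) in the control group and 4290189 ± 79756 (SD, n = 3) in the other. Between 16824 and 17379 genes had at least 1 count in a library. Ribosomal protein genes and their pseudogenes took 49.2% ± 2.9 (SD, n = 3) of the control counts and 50.9% ± 1.5 (SD, n = 3) of the counts in the libraries labelled si-CPSF3. Mitochondrial transcripts took 7.10% ± 0.34 and 7.82% ± 0.75 in the same order.

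The targeted gene was examined first, as a check on the labels. CPSF3 was not lower in the libraries labelled si-CPSF3. Its counts were 20, 50 and 36 in control replicates 1, 2 and 3 and 56, 38 and 66 in the libraries labelled si-CPSF3. The normalised levels (CPM, counts scaled to library size) were 8.10 ± 3.15 and 13.0 ± 3.54 CPM (SD, n = 3 in each group), a fold change of 1.59 with a 95% interval of 0.998 to 2.55. The log2 fold change of 0.67 (SE 0.32) did not pass the test (edgeR adjusted p = 0.329), and a two-sided exact permutation test gave p = 0.3, where 0.1 is the smallest value 3 against 3 libraries allow. The deposited FPKM values of CPSF3 were 4.76 ± 1.82 and 6.31 ± 1.895 (SD, n = 3). The gene lies on chromosome 2 from 9423654 to 9473101 (GRCh38). Because the level of the target goes against the label, the groups are named below only by their labels, and "higher" and "lower" mean higher or lower in the libraries labelled si-CPSF3 than in those labelled control.

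**Figure D1:**
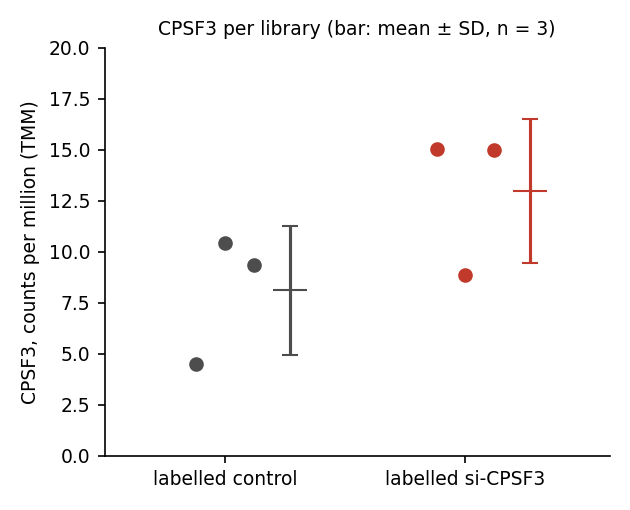
Normalised CPSF3 level in CPM (vertical axis) in each library, by the label of its group; points are libraries and bars are the mean and SD of 3. The 3 libraries labelled si-CPSF3 average 13.0 and the 3 control libraries 8.10, and the ranges overlap.

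The design asks which transcripts differ between the group labelled si-CPSF3 and the control group. Of 11069 genes tested, 247 differed at an adjusted p under 0.05, 80 of them higher and 167 lower. A log2 change of at least 1 was seen in 39 of the higher and 104 of the lower genes. The most abundant transcript to fall was MT2A, a metallothionein that binds zinc and copper, which took 3.67% ± 0.49 of the control counts and 0.877% ± 0.060 of the counts in the libraries labelled si-CPSF3 (SD, n = 3). MT1X, another metallothionein, fell from 1496 ± 140 to 361 ± 27.5 CPM (log2 fold change -2.05, SE 0.16, adjusted p = 1.46e-05). EGR1, an immediate-early transcription factor, rose from 4.02 ± 1.55 to 33.8 ± 7.15 CPM (log2 fold change 3.08, SE 0.28, adjusted p = 4.41e-05). RBCK1, a subunit of the linear ubiquitin ligase complex, rose 3.48-fold, and TNFRSF10B, the TRAIL death receptor DR5, rose 3.47-fold.

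Further higher genes of large size were TSC22D3, a glucocorticoid-induced leucine zipper protein (log2 fold change 1.71), HLA-B of the class I antigen presentation complex (1.81), the zinc finger gene ZNF592 (1.66), the kinase gene RSKR (1.66), the phosphatase gene PTPN1 (1.67), the splicing regulator PTBP2 (1.88), the neuronal kinesin KIF5A (1.65), the hedgehog pathway factor GLI1 (1.63) and SPANXA2 (1.34). PTPN1 varied widely in the libraries labelled si-CPSF3, at 32.4 ± 23.0 CPM (SD, n = 3). Lower genes included KDM7A, a histone demethylase (log2 fold change -3.88, SE 0.40, adjusted p = 0.000116), DOCK5, an exchange factor for the GTPase Rac (-2.33), the matrix protein SPARC (-2.22), the metalloproteases ADAM9 (-1.98) and ADAM12 (-1.90), and CALD1, an actin-binding protein (-1.36). LOC107987457 had 0 counts in the 3 control libraries and 125 in the 3 others, at least 43.9-fold higher against a floor of 3 counts over the group. METTL9, a methyltransferase, passed the test as lower, but the table holds the gene on several rows: 1 row of the table held 42, 55 and 42 counts in the control libraries and 0 in the others, while a second row held 0 in the control libraries and 38, 33 and 64 in the others, and their sum did not differ (log2 fold change 0.027, adjusted p = 0.977). With 1 library left out in turn, PTBP2 passed in 0 of 6 fits, RSKR and GLI1 in 1, PTPN1, KIF5A, ADAM9 and ADAM12 in 2, ZNF592 in 5, and the other genes named here and in the paragraph above in all 6.

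**Figure D2:**
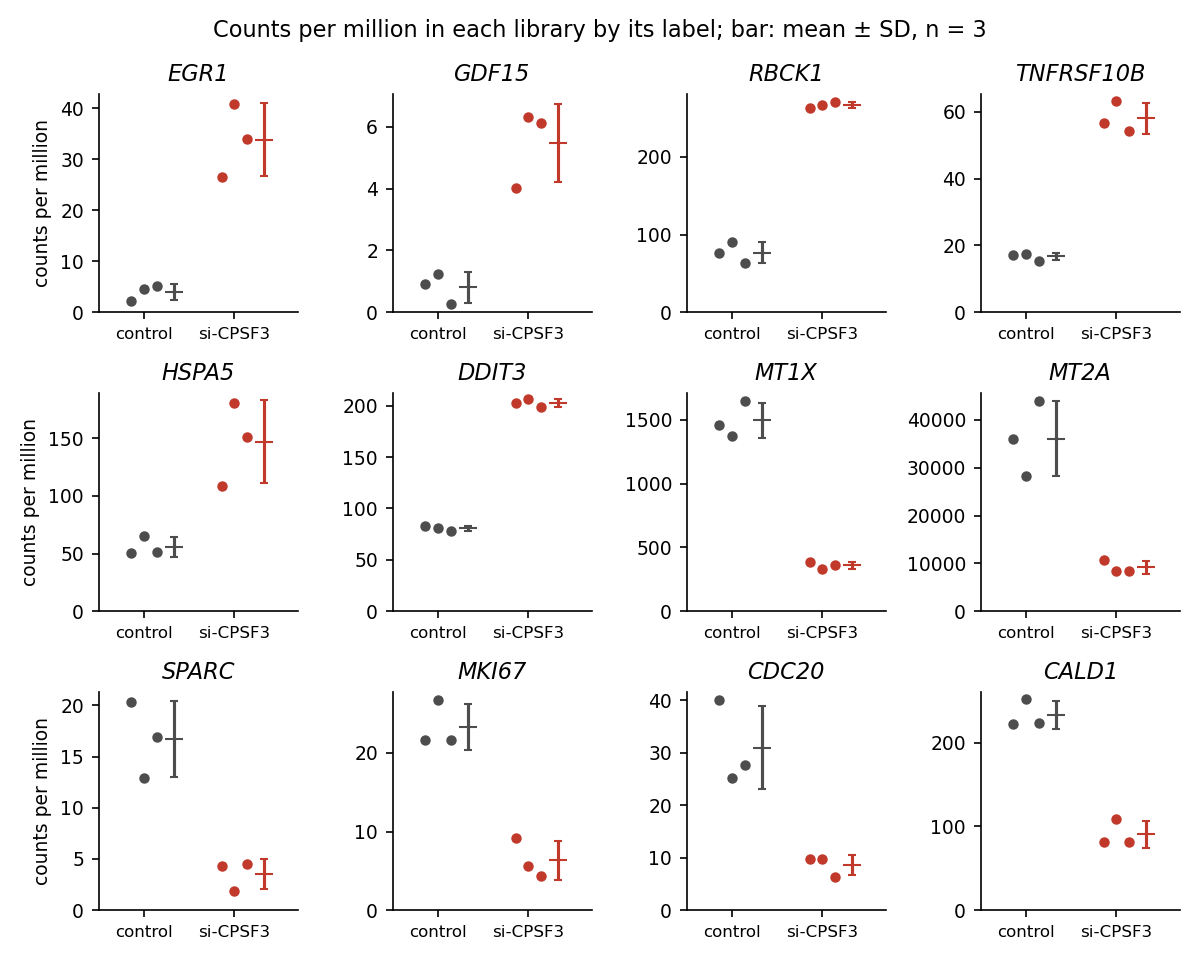
Normalised levels in CPM (vertical axes, each from 0) of 12 genes in each library, by label; points are libraries and bars are the mean and SD of 3. The libraries of the 2 groups do not overlap for any of the 12 genes, which the rule for naming genes required of most of them. Examples are MT1X at 1496 against 361 and EGR1 at 4.02 against 33.8 on average.

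Metallothioneins, HLA genes, histone genes, ribosomal protein genes, the SPANX family and LOC107987457 have near-identical copies, and how the authors' counting shared reads between them is not given in the sources used here, so single members are uncertain. Among the 247 calls, 11 were of genes held on several rows of the table, and 8 of these passed again when the distinct rows were summed; METTL9, LOC283299 and RGL2 did not, and the log2 fold change of HLA-B went from 1.81 to 1.03. Groups did not overlap for 21.2% of the genes tested, where chance gives 10%. Scaled by library totals alone, 190 genes passed and 18.9% of them were higher, against 32.4% with composition factors, as that scaling moved the median of all genes to -0.10.

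Among the lists fixed beforehand, genes of the G2 and M phases of the cell cycle made up the one with the most calls. Of 38 measured members, 12 fell and 0 rose (23 fell and 1 rose when adjusted over the list alone), and the median log2 fold change was -0.95. The proliferation antigen MKI67 went from 23.3 ± 2.91 to 6.35 ± 2.49 CPM, and CDC20, an activator of the anaphase-promoting complex, from 30.9 ± 7.93 to 8.61 ± 1.96 (SD, n = 3). The spindle genes GTSE1 (log2 fold change -2.14), AURKB (-2.10) and NUSAP1 (-1.85) fell as well. Genes of the G1/S transition and S phase had a median of -0.17, and 3 of 26 fell (3 also when adjusted over the list alone), all subunits of the replicative helicase: MCM4 (-1.51), MCM5 (-1.20) and MCM2 (-1.14). The set test camera called both lists lower (adjusted p = 2.7e-13 for G2/M and 0.00873 for G1/S). Neither passed with the correlation between members estimated (adjusted p = 0.170 with an estimated correlation for each), a setting in which 0 lists passed. The estimate was 0.076 for G2/M and -0.034 for G1/S, so for G1/S it lay below the preset 0.01. Fry called both lists (adjusted p = 0.00605 by fry for each). MKI67, CDC20, GTSE1 and MCM4 passed in all 6 fits that left out 1 library, NUSAP1 in 3, AURKB in 2, and MCM2 and MCM5 in 0.

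Stress-response genes moved in both directions. In the list of ATF4 and integrated stress response genes, 2 of 24 rose and 1 fell (3 and 1 when adjusted over the list alone). DDIT3, the transcription factor CHOP, went from 80.7 ± 2.45 to 203 ± 3.79 CPM and TRIB3, a pseudokinase induced by CHOP, from 202 ± 23.3 to 422 ± 12.9 (SD, n = 3), while SHMT2 of serine metabolism fell (log2 fold change -0.67). Of 19 endoplasmic reticulum chaperone and unfolded protein response genes, 1 rose (1 when adjusted over the list alone), the chaperone HSPA5, by 2.64-fold (log2 fold change 1.40, adjusted p = 0.00133). Among 19 p53 target genes, TNFRSF10B and GDF15, a stress-induced cytokine (log2 fold change 2.68 from 0.805 CPM), rose and the kinase gene PLK2 fell (-1.83), with 2 higher and 1 lower when adjusted over the list alone. In the BCL2 family list, 1 of 19 rose, the survival factor MCL1 (0.77), and 1 fell, BIRC5 (-0.94), which is also a mitotic gene (2 and 1 when adjusted over the list alone). Camera called none of these 4 lists (adjusted p = 0.243, 0.676, 0.337 and 0.328 in this order). DDIT3, TRIB3, HSPA5 and TNFRSF10B passed in all 6 fits that left out 1 library, PLK2 in 4, GDF15 in 3, MCL1 and SHMT2 in 1 and BIRC5 in 0.

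The inflammatory, heat shock and ribosome biogenesis lists had medians below 0, with few single calls. In the NF-kB and inflammatory list, 2 of 11 fell (5 when adjusted over the list alone) with a median of -0.57: the chemokine CCL2 (log2 fold change -2.55, from 6.69 ± 4.86 CPM) and the mitochondrial superoxide dismutase SOD2 (-1.51). Of 12 heat shock genes, 1 fell (3 when adjusted over the list alone), HSP90AA1 (-0.73), and the median was -0.32. Of 39 MYC target and ribosome biogenesis genes, 1 fell (1 when adjusted over the list alone), the pseudouridine synthase PUS7 (-1.15), with a median of -0.28. Camera called the 3 lists lower (adjusted p = 0.000653, 0.00873 and 0.00873), and none passed with the correlation estimated (adjusted p = 0.170, 0.349 and 0.170 with an estimated correlation). The estimates were -0.018, 0.071 and -0.015, and 0 lists of any kind passed in that setting. Fry called all 3 (adjusted p = 0.00879, 0.0150 and 0.00605 by fry). SOD2 passed in all 6 fits that left out 1 library, CCL2 and HSP90AA1 in 2 and PUS7 in 0.

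Replication-dependent histone genes, whose pre-mRNA is also cut by the CPSF3 endonuclease, had the highest median of the tested lists that were fixed beforehand. Of 61 such genes, 14 had enough counts to be tested. Of these, 2 rose and 0 fell (6 rose when adjusted over the list alone). The median log2 fold change was 0.52, with 11 members above 0 and 3 below. The most abundant member, H4C3, was at 0.29 (edgeR adjusted p = 0.469). H2BC5 went from 10.8 ± 1.33 to 32.0 ± 6.68 CPM (log2 fold change 1.56, adjusted p = 0.00142) and H2BC12 from 29.1 ± 6.10 to 53.1 ± 10.6 (0.87, adjusted p = 0.0312). Camera called the list higher (adjusted p = 0.00511), which did not hold with the correlation estimated (adjusted p = 0.579 with an estimated correlation), and H2BC12 passed in 2 of the 6 fits that left out 1 library. The other factors of mRNA 3' end cleavage and polyadenylation gave 0 calls among 22, with the poly(A)-binding protein gene PABPN1 at -0.40 (adjusted p = 0.168) and SSU72 at 0.56 (adjusted p = 0.0824). The Integrator complex gave 0 of 13, with INTS6 at -0.07 and INTS4 at -0.23, and histone mRNA processing factors gave 0 of 9, with SRRT at -0.26 and LSM10 at -0.17; adjusted over the list alone, the counts were 0, 0 and 1 in the order of these 3 lists.

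Cytosolic ribosomal protein genes had a median log2 fold change of 0.10, and 0 of 83 passed singly, also when adjusted over the list alone. The 2 most abundant were RPL13A (0.36, adjusted p = 0.485) and RPL31 (0.27, adjusted p = 0.638). Camera called the list higher (adjusted p = 0.0246), but not with the correlation estimated (adjusted p = 0.770 with an estimated correlation), nor scaled by library totals (adjusted p = 0.057, median 0.02), nor without control replicate 1 (0.245), control replicate 2 (0.436) or replicate 1 of the libraries labelled si-CPSF3 (0.211). The mitochondrially encoded mRNAs gave 0 of 13 (1 higher when adjusted over the list alone), with COX3 at 0.72 (adjusted p = 0.0646) and ND1 at 0.21.

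Among genes of cell identity and matrix signalling, single members fell without a call of their list. In the TGF-beta and YAP target list, 3 of 16 fell and 1 rose (4 and 2 when adjusted over the list alone): the matricellular genes CCN2 (log2 fold change -1.30) and CCN1 (-1.17) and the receptor tyrosine kinase AXL (-0.77) fell, and ID1, a BMP and TGF-beta target, rose (0.89). Of 12 mesenchymal genes, SPARC fell and 0 rose (2 fell when adjusted over the list alone). The 7 epithelial genes measured gave 0 calls, also when adjusted over the list alone, with KRT8 at 0.07 and KRT18 at -0.38. Basal urothelial markers were represented by 3 genes, of which CD44, a hyaluronan receptor, fell (-0.70; 1 when adjusted over the list alone), and luminal markers by 4 genes with 0 calls in either count, XBP1 at 0.33 and PPARG at 0.04. Camera gave adjusted p = 0.937 for the TGF-beta list, 0.328 for the mesenchymal list and 0.934 for the epithelial list. SPARC and ID1 passed in all 6 fits that left out 1 library, CCN2 in 5, CCN1 and AXL in 3 and CD44 in 2.

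Lysosomal, metabolic and signalling lists were not called by camera. In the autophagy and lysosome list, 1 of 25 rose, MAP1LC3B (log2 fold change 1.01), which encodes the autophagosome protein LC3B, and 2 fell, the protease gene CTSB (-1.11) and ATG7 (-0.74), with 2 and 3 when adjusted over the list alone. Immediate-early and AP-1 genes gave EGR1 and SPRY4 (1.27), an inhibitor of receptor tyrosine kinase signalling, higher of 23 (4 higher and 1 lower when adjusted over the list alone). Their median was -0.06 while their mean was 0.14. The ferritin light chain FTL (0.67) rose among 21 NRF2 targets (2 higher and 2 lower when adjusted over the list alone). The glycolytic genes PGAM1 (-0.74) and PFKP (-0.66) fell among 25 hypoxia and glycolysis genes (2 when adjusted over the list alone). The respective camera adjusted p values were 0.499, 0.783, 0.711 and 0.243. CTSB and SPRY4 passed in all 6 fits that left out 1 library, MAP1LC3B in 4, ATG7 in 2 and FTL, PGAM1 and PFKP in 1.

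The other lists gave 0 calls over all genes tested. These were 14 interferon-stimulated genes (IRF1 at 0.21, ISG15 at -0.32), 19 cholesterol synthesis genes (SREBF2 at -0.20, SQLE at 0.22), 44 nuclear genes of oxidative phosphorylation (COX7C at 0.14, COX8A at -0.02), 18 DNA repair genes (ATM at -0.29, RAD50 at 0.08) and 37 splicing factors (SNRPF at 0.06, PRPF19 at -0.13). Adjusted over the list alone, 1 cholesterol synthesis gene was lower and the other 4 lists again gave 0, and camera gave adjusted p = 0.676, 0.777, 0.676, 0.243 and 0.711 in this order. Markers of leukocytes, checked as a sign of RNA from other cells, had 3 measured members with 0 calls (1 lower when adjusted over the list alone), CD68 at 25.3 ± 3.88 and 14.1 ± 2.49 CPM (adjusted p = 0.0524) and LYZ at 15.7 ± 1.77 and 17.1 ± 1.63. None of the erythroid and endothelial markers was tested.

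**Figure D3:**
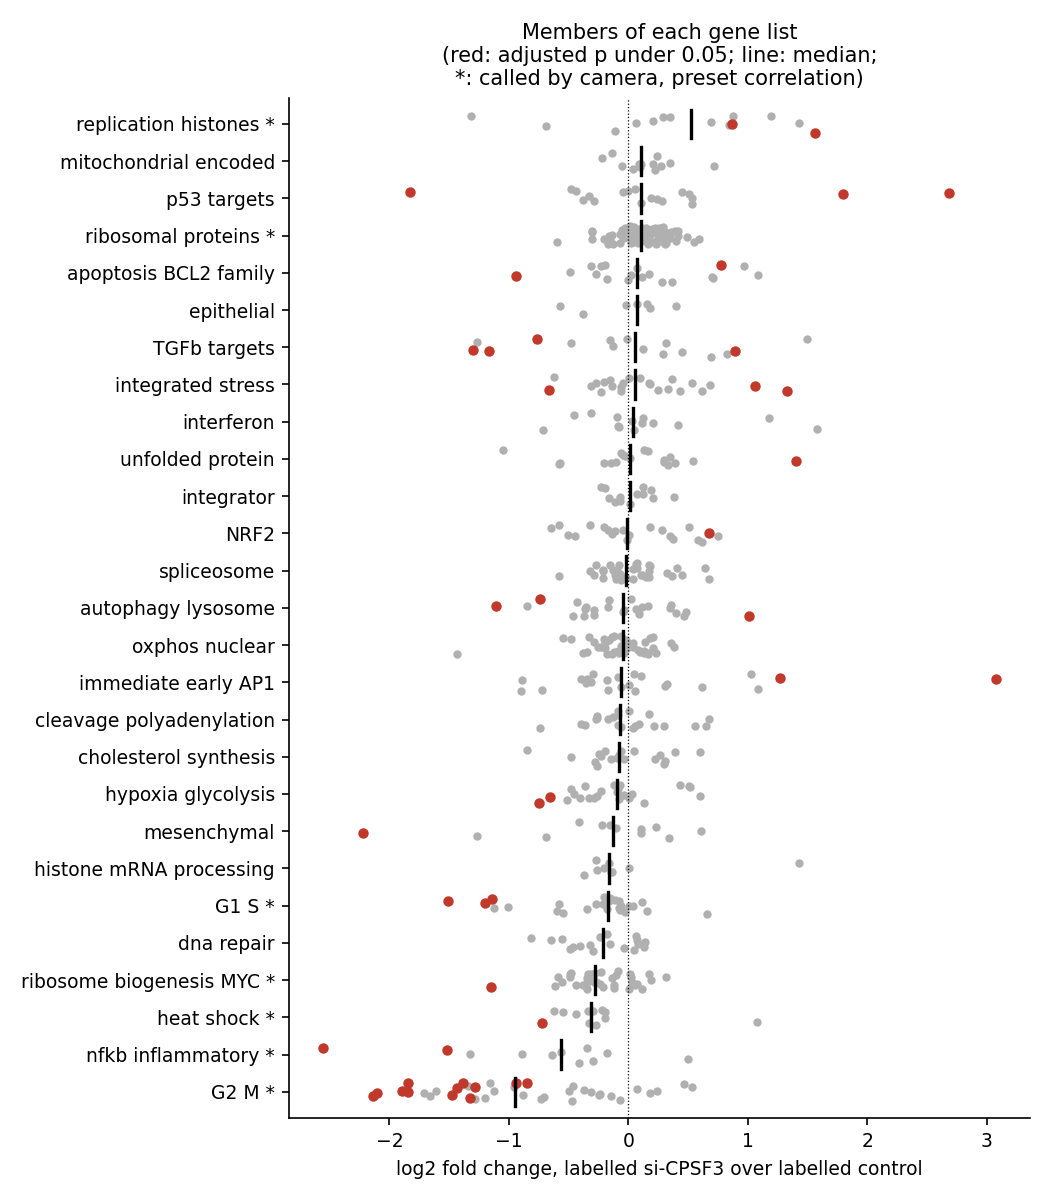
Log2 fold change of each measured member (horizontal axis, libraries labelled si-CPSF3 over libraries labelled control) in the lists with at least 5 tested members; red points passed an adjusted p of 0.05, vertical lines are list medians, and an asterisk marks lists called by camera with its preset correlation. Among these lists, all fixed beforehand, the G2/M list lies lowest with a median of -0.95 and the histone list highest with 0.52.

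The number of changed genes was lower with any 1 library left out, where fewer samples were fitted. It was 122, 199 and 168 without control replicates 1, 2 and 3. It was 115, 85 and 176 without replicates 1, 2 and 3 of the libraries labelled si-CPSF3. On the deposited FPKM values, 41 genes passed with a pseudocount of 1 and 31 with a pseudocount of 0.1.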

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

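Before the data were examined, all alternatives but 3 had been fixed; the fits of all rows, of summed rows and without ribosomal protein, mitochondrial and MALAT1 genes were chosen after seeing the data. CPSF3 stayed higher and short of the threshold in all 19 alternatives, at 0.38 (without control replicate 1) to 0.91 with 1 library left out and 0.36 on log2(FPKM + 1). Against 247 changed genes (80 higher, 167 lower; 39 and 104 by at least 1 log2 unit), other count scalings, DESeq2 (286; 1073 genes without an adjusted p), limma-voom (208) and the stricter filter (272) stayed within 1.5 times in total. Library totals gave 36 higher genes, 24 of them by 1 log2 unit. Without a filter the counts were 547, 232 higher and 315 lower, with 113 and 178 past 1 log2 unit, and all 247 passed again among 21195 genes. On log2(FPKM + 1) they were 41, 11, 30, 11 and 29 in the same order, and on log2(FPKM + 0.1) 31, 12, 19, 12 and 19; the cause was not tested. Against a 1.2-fold change 132 passed. How genes on several rows are handled mattered: 190 passed with all rows as deposited and 328 with distinct rows summed. With 1 library left out, 85 to 199 genes changed, 30 to 69 higher and 55 to 130 lower, with 22 to 50 and 46 to 90 past 1 log2 unit; fewer samples were fitted. The lowest counts of each came without replicate 2 of the libraries labelled si-CPSF3; without control replicate 3, 100 were lower. Of 56 named genes past the threshold, 26 passed in all 6 such fits, 5 in 0, and 15 on both FPKM scales. On neither FPKM scale passed 38, among them DDIT3, TRIB3, HSPA5 and MKI67, which passed in all 6 such fits.

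With the replicate block 147 genes changed, 41 higher (24 by 1 log2 unit) and 106 lower, 143 of them among the 247. Whether the numbers pair the libraries stays open. Deviations of same-numbered libraries from their group means correlated across genes at 0.19, 0.13 and -0.06. Control replicate 2 correlated at 0.14 with replicate 3 of the other group, and control replicate 3 correlated best with its replicate 1 (0.08). With 3 libraries per group, such deviations are too few to decide. The block changed no list call.

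Of the 7 lists called, 0 were called with an estimated correlation, so that setting does not tell these lists apart. Fry called 5 (not histones and ribosomal proteins), and 6 or 7 were called with 1 library left out. METTL9 turned to 8.53 with all rows as deposited and 0.0271 with its rows summed, as 2 rows of the gene hold counts in opposite groups. At this depth, 54% of simulated 2-fold changes were recovered, so changes of that size can be missed.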

Other observations

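The gene groups of the next 2 paragraphs were picked after the calls were seen, as were the tests of the CPSF3 interval, of exchanged group names, of summed METTL9 rows, of word composition and of neighbouring genes. The search of 3' UTR words was chosen after the calls and before its own result was seen. The conditions set for the histone and neighbouring gene tests were made stricter after their values were seen. The condition for downstream genes is given as first set. Directions are again those of the libraries labelled si-CPSF3 over control, with CPSF3 itself not lower.

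Several genes of the actin cytoskeleton and cell adhesion fell. In a list of such genes, written after the calls, 13 of 48 measured members fell and 1 rose. CALD1 fell from 233 ± 16.8 to 90.5 ± 15.8 CPM, the LIM-domain gene FHL2 from 126 ± 2.70 to 56.1 ± 1.23, the membrane-repair gene MYOF from 41.5 ± 2.60 to 16.4 ± 2.68 and the non-muscle myosin heavy chain MYH9 from 71.4 ± 6.33 to 35.5 ± 9.34 (SD, n = 3). The caveolar gene CAVIN3 had a log2 fold change of -1.77 and the filamin gene FLNA one of -0.74, while the tropomyosin gene TPM2 rose (0.68) and TPM4 fell (-0.75). The main actin genes ACTB (0.00) and ACTG1 (-0.07) did not pass. The 34 members without a call, 12 above and 22 below 0, had a median of -0.10 and were not called by camera (adjusted p = 0.224). Leaving out the called genes draws the rest toward 0, so this test leaves open whether the change reaches further.

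Several transcripts of neuronal and secretory vesicle proteins were higher. The secretory granule protein CHGB went from 0.295 ± 0.347 to 7.09 ± 1.64 CPM, the neuropeptide precursor VGF from 70.3 ± 12.9 to 136 ± 10.3, and the vesicle protein SYP from 7.80 ± 1.17 to 17.9 ± 1.71 (SD, n = 3), and the GTPase gene RAB39B had a log2 fold change of 1.22. PCDH17 had 0 control counts against 49, at least 17.2-fold higher against a floor of 3 counts over the group. A list of 47 such genes and of neuronal regulators and transport genes, written after the calls, includes the 5 named above. Only 15 of the 47 could be tested, of which 7 rose and 0 fell, a share set in part by that choice. Among the 7 were KIF5A and PTBP2, which passed in 2 and 0 of the 6 fits that left out 1 library. The 8 others, 4 above and 4 below 0, had a median of -0.04 (camera adjusted p = 0.726), with the same limit. PTBP1, which represses PTBP2 splicing, fell (log2 fold change -0.83, adjusted p = 0.01003) where PTBP2 rose. PTBP2 passed on neither FPKM scale, which was so for 38 of the 56 named genes past the threshold.

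CPSF3 was not lower where the labels name it as the target. Too few reads do not account for that: the 95% interval of the fold starts at 0.998, above the 0.5 that a 2-fold reduction would give. An exchange of the 2 group names remains open, because the higher level in the libraries labelled si-CPSF3 did not pass the test (adjusted p = 0.329). A reduction that had ended before RNA was collected, or one of the protein alone, was not tested.

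Genes whose 3' UTR holds the word TAAATCA were lower. Among 6837 genes and 16218 words it had the lowest score, -7.49, against -4.39 at the 5th percentile of the lowest scores of 100 shuffles, and TTAAATC, which overlaps it, came next at -6.13. Without adjustment for UTR length, GC content or expression, the median log2 fold change was 0.00 in 5683 genes without the word. It was -0.06 in 892 with 1 copy and -0.10 in 262 with at least 2. These medians, and the shares that follow, do not separate the word from UTR length or base content. The word was also picked as the lowest scorer on these same fold changes, so they describe it and are no separate support. The word stood in 43 of 134 lower genes (32.1%), in 6 of 61 higher genes (9.84%) and in 1105 of 6642 genes without a call (16.6%), so most lower genes lack it. Lower genes with the word included ADAM9, SOD2, CALD1, STAT3, SMAD3 and CD44. In the 346 genes that hold it outside the 3' UTR alone, the score was -2.46.

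An siRNA can lower transcripts that match bases 2 to 8 of either of its strands in their 3' UTR, so a candidate explanation is such a seed in the libraries labelled si-CPSF3. The tables argue against base composition, as 104 other words of the same bases had a median score of 0.16 and a lowest one of -4.22, and against a single library, as the score stayed at or below -6.14 with each library left out. If bases 2 to 8 of the siRNA strand that pairs with CPSF3 match TAAATCA in full, the CPSF3 mRNA should hold that word. It was in 0 of 5 annotated transcripts, which argues against that full match only. The overlapping word TTAAATC and its reverse complement were not sought in CPSF3, so a shifted seed in either strand stays open. For a full match to the other strand, the mRNA should hold the reverse complement TGATTTA. That word was in 3 transcripts, in coding exon 3 of the principal one (chromosome 2, 9429976 to 9429982, GRCh38). Of 924 transcripts of like length, 12.8% hold TGATTTA and 22.8% hold either word. The sequences of the siRNAs were not analysed here, and a microRNA with the same seed was not tested. Of the 10 splits of the libraries, 1, the real one, scored as far from 0 (-7.37; next -5.74), too few for a share under 0.05, and mixed splits gave scores down to -5.98 for other words, so shuffles of genes understate the noise.

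The count of 247 changed genes was likewise reached by 1 of the 10 splits, the real one, where the highest other split gave 1 gene; 10 splits are too few for a share under 0.05.

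The METTL9 call reads as a loss in the libraries labelled si-CPSF3, yet the 2 rows of the gene summed to a log2 fold change of 0.0271. Assignment of its reads to another row of the same gene is therefore a candidate explanation. Why the rows hold counts in opposite groups was not tested.

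A loss of CPSF3 activity would let transcription run past cleavage sites and leave histone transcripts uncut. The median log2 fold change of 718 genes just downstream of a tested gene was -0.0037, inside the 95% range of matched lists from -0.045 to 0.026. These genes as a set therefore did not rise, the outcome that the condition first set named for no such running on. The test cannot decide this, as each downstream gene was itself expressed and its counts mix any run-on reads with its own. A rise in a small part of them would not show in a median. The rise of histone genes that a loss of CPSF3 activity predicts was called by camera (adjusted p = 0.00511). It was not called with the correlation estimated (adjusted p = 0.579 with an estimated correlation) or by fry (adjusted p = 0.189). As CPSF3 mRNA was not lower, the predictions for downstream genes and for histone genes stay open.

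Some called genes stood close together on the genome. Of 247 calls, 22 had another gene called in the same direction within 100 kb, against a median of 10 and a 95% range of 3 to 20 in 10000 random lists matched on expression. Without MT2A and MT1X, whose sequences are alike, 20 remained against a range of 2 to 20, so changes shared by neighbours stay open. On chromosome 12, GLI1, DDIT3 and KIF5A rose within 57459785 to 57586633, while MARS1 between them did not pass (log2 fold change 0.17), and on chromosome 20 RBCK1 starts 10.7 kb from the end of TRIB3. Pairs of lower genes included PRKDC with MCM4 and STAT3 with CAVIN1. Taken by direction, 8 higher calls had such a neighbour (random median 2, upper end of the 95% range 6). So did 14 lower calls (random median 8, upper end of the 95% range 17). The higher calls thus lay above their random range and the lower calls inside theirs.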
